A study of Mus musculus with 2 samples.

How the data were processed

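The series profiled DNA associated with PHLPP1 in mouse bone marrow-derived macrophages. PHLPP1 is a protein phosphatase known for dephosphorylating the kinase AKT. The macrophages were grown from bone marrow with M-CSF, the growth factor of this lineage, at 20 ng/ml, per the labels' protocols. There were 2 libraries, 1 per group: untreated cells and cells given IL-4, the cytokine that drives alternative activation of macrophages, at 20 ng/ml for 4 h. The series design describes wild-type cells, and both libraries were taken as wild-type. In CUT&Tag, an antibody directs a protein A/G-Tn5 transposase to chromatin in permeable cells, and DNA next to the bound sites is tagged for sequencing. The protocol in the labels names a commercial kit from Vazyme, concanavalin A beads and an antibody to PHLPP1 from ProteinTech. No library from PHLPP1-deficient cells, no control antibody library and no input library was analysed here.

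The authors deposited 1 peak list per library in the narrowPeak layout. Peaks were called per library, since each sample has its own list. The submitters' processing notes name Bowtie 0.12.8, MACS2 2.2.7.1, DiffBind and the mouse build mm10, without the role or order of each tool. How duplicate fragments were treated, the fragment size used and the control used in peak calling are not given in the sources used here. Each deposited peak has a start, an end and a summit position, counted here from 1. The deposited score of each peak equalled its −log10 p times 10, with decimals dropped, in 100% of the entries of both lists. The deposited fold enrichment is a linear ratio of the fragments at the summit to the authors' local background. The deposited −log10 p and −log10 q are the authors' caller's own values for each peak. They were used to describe, rank and filter peaks within a list. The 2 lists were also set side by side at the same thresholds, but these values do not test a difference between the groups. The lowest −log10 p was 2.00 in both lists, which places the threshold of the authors' calling at p 0.01 rather than at a q value.

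The number of fragments at each summit and the local background were solved from the deposited fold and −log10 p. This took the fold as (fragments + 1)/(background + 1) and p as the upper tail of a Poisson distribution. A whole number of fragments was found within 0.01 of the deposited −log10 p for 100% of the entries in both lists. The lowest local background describes the depth of a library times its fragment length. Total reads per library were not used here. Fragments from PCR are not independent molecules, so the exact Poisson intervals given with fragment numbers cover counting error only.

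Entries of the same interval with several summits, 203 in the untreated list and 654 in the IL-4 list, were reduced to the summit with the highest −log10 q. Peaks counted as shared when at least 1 bp overlapped a peak of the other list. Chance overlap was measured by shifting every peak along its chromosome by 20 steps of 5 Mb, up to 100 Mb, with the end joined to the start. Shifted peaks can fall in assembly gaps, so this chance level can be slightly low. Gene positions came from the RefSeq gene table of assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y used. No peak of either list lay on Y. That table gives no strand. The design fixed before the data were examined called for promoters, and a summit within 1 kb of either annotated end of a protein-coding gene was used in its place. A gene-end peak can therefore lie at the start or at the 3′ end of a gene, and a peak near ends of 2 genes counted for both. Each gene was placed in 1 of 4 classes by whether a gene-end peak stood in both lists, in the IL-4 list only, in the untreated list only or in neither. "IL-4-only" describes the lists and is not a tested change. At a stricter threshold it means that no untreated peak passed that threshold, not that none was listed.

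A total of 19 gene lists was fixed before the data were examined: alternative activation, IL-4 receptor signalling, PHLPP and AKT pathway, inflammatory, interferon response, macrophage identity, lysosome and autophagy, lipid metabolism, glycolysis, chromatin regulators, housekeeping, neutrophil, T and NK cell, B cell, dendritic cell, stromal, erythroid, neuron and hepatocyte genes. Of their 336 genes, 334 were measured. The other 2 were not used here. Batf3 stands in both the alternative activation and the dendritic cell list. The share of a list's members with an IL-4-only gene-end peak was placed among 10000 random lists of the same size, matched on decile of gene length. Matching on GC content was planned and was not possible without a genome. Peak density was the median over a list of log2((IL-4 peaks + 1)/(untreated peaks + 1)), counting summits within 50 kb of either gene end, and was placed among 10000 random lists matched on decile of total peaks. These percentiles describe the 2 libraries and were not corrected for the 19 lists. Random lists were not matched on expression. Motif shares at summits were planned and not run, because no genome was used here.

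Genes named in the text followed a rule fixed before the data were examined. It took 16 genes of PHLPP1 and IL-4 biology, up to 3 IL-4-only and up to 2 untreated-only members of each list with the highest −log10 q, the 8 strongest IL-4-only, 5 strongest untreated-only and 5 strongest shared genes of each list, and the strongest peaks away from gene ends. Some genes that the rule names are not reported here. Other genes and regions were named after their values were seen, and the text says so.

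With 1 library per group, no p-value, SE or count of changed genes was computed. Wilson 95% intervals around shares of peaks cover counting error of peaks only. The alternatives covered stricter peak thresholds, other overlap rules, other windows, lists of equal length and unmatched random lists. A threshold of q 0.05, a minimum of 4 fragments and the list density without chromosome X were added after the data were seen. So were the pooling of lists of other cell types and a −log10 q of at least 5 for the classes of the gene lists. The methods were tested on simulated data: fragments were recovered in 100% of 4920 made-up peaks, planted overlaps in 100% of 10000, planted gene-end peaks in 100% of 200 genes, and 5% of 100 random lists fell in the top 5%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.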

Results

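PHLPP1-associated DNA was mapped by CUT&Tag in bone marrow-derived macrophages that were left untreated or given IL-4 for 4 h, with 1 library in each group. The comparison asks where PHLPP1 signal lies in the genome with and without IL-4. The untreated list held 149349 peaks covering 32.0 Mb, with a median width of 171 bp. The IL-4 list held 240661 peaks covering 52.1 Mb, with a median width of 164 bp. Because each group had 1 library, differences between the lists have no replicate check, and values are given side by side.

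The strong IL-4 peaks lay mainly at the ends of protein-coding genes, and the strong untreated peaks did not. Among peaks with a −log10 q of at least 5, 461 of 799 IL-4 peaks (57.7%, Wilson 95% interval 54.2 to 61.1) had a summit within 1 kb of a gene end, against 11 of 141 untreated peaks (7.80%, 4.41 to 13.4). Shifted positions gave 3.07% and 2.77%. The strongest of these IL-4 gene-end peaks lay at Smc2, which encodes a condensin subunit, on chromosome 4 from 52438724 to 52439421, across the gene's annotated end at 52439221. It rested on 41 fragments (exact Poisson 95% interval 29.4 to 55.6), and the untreated list had a peak of 15 fragments (8.40 to 24.7) at the same end.

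Other genes with a gene-end peak in both lists are given with their fragment numbers, which are not scaled for the background, 1.46 times as high in the untreated library. Pknox1, encoding a homeodomain transcription factor, had 29 fragments in the IL-4 list and 13 in the untreated list, at −log10 q 22.2 and 6.28. Gpbp1 had 28 and 6 fragments, and Suclg1, encoding a subunit of the citric acid cycle enzyme succinyl-CoA ligase, had 26 and 5, with weak untreated peaks at −log10 q 1.11 and 0.737. Upf2, a gene of nonsense-mediated mRNA decay, had 23 fragments with IL-4 and 21 without. Slc35f5 had 21 and 15. Lars2, encoding the mitochondrial leucyl-tRNA synthetase, had 15 and 22. At Sfi1 the 2 lists had peaks at opposite ends of the gene, and at Lyrm4 likewise, so these do not compare the same site.

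Of the genes with a gene-end peak in the IL-4 list only, Fars2 had the strongest, with 30 fragments and a −log10 q of 23.9 on chromosome 13 from 36117449 to 36118042. Fars2 encodes the mitochondrial phenylalanyl-tRNA synthetase and shares this peak with the neighbouring Lyrm4. Next by −log10 q came 1700030J22Rik with 26 fragments, Ski, a repressor of TGF-β signalling, with 27, Farsb, encoding a subunit of the cytosolic phenylalanyl-tRNA synthetase, with 23, and Fkbp2, which overlaps LOC114841036, with 29. Fntb, encoding the β subunit of protein farnesyltransferase, had 21 fragments, and Ndufa4, encoding a protein of the respiratory chain, had 22. Ndufa4 shares its peak with Phf14. Genes of the untreated list alone had at most 11 fragments among the strongest 5: Cap2, Ptx4 and Ssr1 each had 11 and a −log10 q of 4.26, and 4430402I18Rik and Gm1966 each had 10 fragments and 3.41.

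Counted over 21887 protein-coding genes, 3018 had a gene-end peak in both lists, 7772 in the IL-4 list only, 1954 in the untreated list only and 9143 in neither. Independent lists would share 2451 genes. At a −log10 q of at least 5 the same classes held 11, 564, 1 and 21311 genes. Of the 575 genes with such an IL-4 peak, 572 had it at 1 end and 3 at both ends.

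The gene-end share was higher among stronger peaks of the IL-4 list, with 4.15% at a −log10 q under 1, 13.6% between 2 and 3, 50.1% (46.0 to 54.2) between 5 and 8 and 77.0% (71.1 to 82.0) at 8 or more. In the untreated list it was 3.33% under 1 and 11.9% (5.19 to 25.0) at 8 or more, where the list held 42 peaks. Over all peaks the shares were 5.37% (5.28 to 5.46) with IL-4 and 3.48% (3.39 to 3.57) without, against 3.08% at shifted positions for both. Most peaks of either list lay elsewhere: 41.4% of IL-4 peaks and 41.6% of untreated peaks were inside genes away from their ends, and 53.3% and 55.0% were outside protein-coding genes and their ends.

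**Figure D1:**
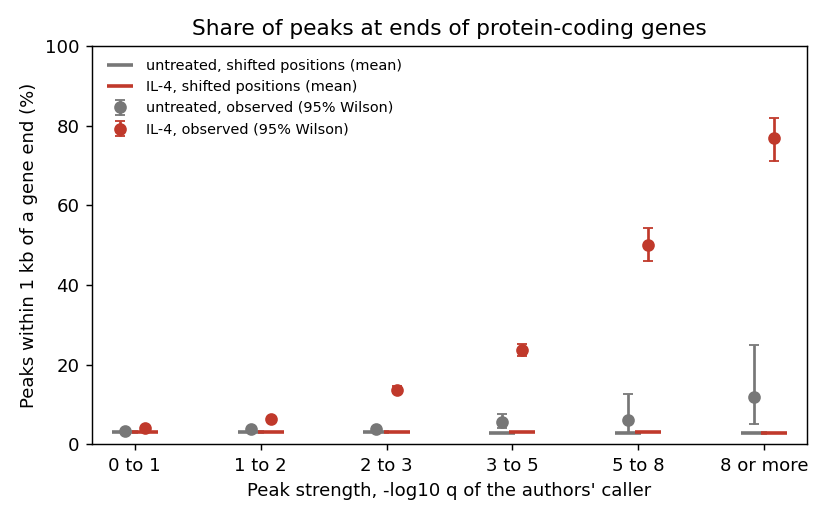
Share of peaks within 1 kb of a protein-coding gene end (percent, vertical axis) by the −log10 q of the peak (horizontal axis) in the untreated (grey) and IL-4 (red) libraries, 1 each, with Wilson 95% intervals for counting error of peaks and dashes for means over shifted positions. The IL-4 share reaches 77.0% in the strongest class, and the untreated share 11.9%.

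Genes of alternative activation had mostly weak gene-end peaks. Klf4, a transcription factor of alternative activation, had the strongest peak of the alternative activation list, with 11 fragments (5.49 to 19.7) and a −log10 q of 4.32 on chromosome 4 from 55532585 to 55533079, in the IL-4 list only. Socs1, a feedback inhibitor of cytokine receptors, had 12 fragments in the IL-4 list and 6 in the untreated list, and the chemokine gene Ccl22 had 7 and 4, at opposite ends of the gene. Weak IL-4-only peaks of 4 or 5 fragments lay at Mrc1, the mannose receptor gene, Irf4, Pparg, Cish, Egr2 and Myc. Retnla, Chil3 and Ccl17, markers of alternative activation, had gene-end peaks of 4, 5 and 4 fragments in the untreated list only, and Arg1, encoding arginase 1, had none in either. Slc7a2, a transporter gene for arginine, and Ptgs1 had IL-4-only peaks of 6 and 7 fragments, and the VEGF receptor gene Flt1 had an untreated-only peak of 6.

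Of the 30 alternative activation genes, 15 had an IL-4-only gene-end peak, 5 had one in both lists, 4 in the untreated list only and 6 in neither. As large an IL-4-only share was found in 11.0% of random lists matched on gene length. At q of at most 0.05, 6 of 30 had an IL-4-only peak, as large a share as in 44.0% of random lists, and at a −log10 q of at least 5 none of the 30 had one, as in 43.1% of random lists.

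The IL-4 receptor pathway and the PHLPP and AKT pathway were in the top 5% of random lists for IL-4-only gene ends over all peaks, as were housekeeping and dendritic cell genes. Stat3, encoding a transcription factor activated by cytokine receptors, had an IL-4-only peak of 18 fragments (10.7 to 28.4) at a −log10 q of 12.8 on chromosome 11 from 100939163 to 100939739. Stat6, encoding the main transcription factor of IL-4 signalling, had an IL-4-only peak of 9 fragments on chromosome 10 from 127660665 to 127660819 that also lies within 1 kb of an end of Nab2. Shc1, an adaptor gene sharing its peak with Cks1b, had 10 fragments, and Jak3, a kinase gene of the receptor, had 8. The receptor gene Il4ra had 4, and Irs1 and Stat5b had untreated-only peaks of 6 and 4. In all, 15 of 22 receptor pathway genes were IL-4-only, as large a share as in 0.61% of random lists.

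Phlpp1 itself, on chromosome 1 from 106171869 to 106394245, had gene-end peaks in both lists, of 6 fragments with IL-4 and 4 without, near the same end but not overlapping. Gsk3a, encoding a kinase inhibited by AKT, had an IL-4-only peak of 12 fragments (6.20 to 21.0) at a −log10 q of 6.34 on chromosome 7 from 25237752 to 25238494. Tsc1, a restrainer of mTOR, had an IL-4-only peak of 8 fragments, and Tsc2 had an untreated-only peak of 8. Of 24 genes of this pathway, 15 were IL-4-only, as large a share as in 1.04% of random lists. Neither pathway was in the top 5% of random lists matched on gene length at q of at most 0.05, where 7 of 22 and 8 of 24 genes were IL-4-only and 12.5% and 5.56% of matched random lists reached these shares, and 6.54% and 3.88% of unmatched ones. The PHLPP and AKT pathway was also outside it with lists of equal length, at 6.08%. At that q a gene such as Phlpp1, Socs1 or Ccl22 counts as IL-4-only when its untreated peak is weaker than the threshold.

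Housekeeping genes had a high share of IL-4-only gene ends over all peaks and at q of at most 0.05. Polr2a, encoding the largest subunit of RNA polymerase II, and the ribosomal protein gene Rpl13a had IL-4-only peaks of 9 fragments each. Polr2a shares its peak with Slc35g3. Of 18 housekeeping genes, 12 were IL-4-only over all peaks, reached by 0.99% of random lists. At q of at most 0.05, 8 of 18 (44.4%) were, against a median of 16.7% in random lists, and 0.59% of random lists reached this share. It was the only list in the top 5% of matched random lists at that threshold. At a −log10 q of at least 5, 0 of 18 were IL-4-only, as in 63.4% of random lists.

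Acadm, Eno1 and Hdac2 had IL-4-only gene-end peaks past a −log10 q of 5, and the other genes of metabolism and chromatin named here did not. Acadm, encoding a dehydrogenase of fatty acid oxidation, had 14 fragments at a −log10 q of 6.11, Nr1h2, the LXRβ gene sharing its peak with Pold1, had 12 at 4.92 and Srebf2, a regulator of sterol synthesis, had 9 at 4.19. The glycolytic gene Eno1 had 10 fragments at 5.15, Gapdh 8 at 1.84 and Pgam1 5 at 1.26. The histone deacetylase gene Hdac2 had 11 at a −log10 q of 5.94 and Suz12, of Polycomb repressive complex 2, had 7 at 2.31. The H3K4 methyltransferase gene Kmt2d, sharing its peak with Prkag1, had 8 at 1.84. Fabp4, a fatty acid carrier gene, had an untreated-only peak of 8 fragments. IL-4-only gene ends were found for 13 of 23 lipid, 7 of 17 glycolysis and 12 of 24 chromatin genes, with 5.03%, 48.5% and 16.0% of random lists as high. Lipid genes were in the top 5% of random lists not matched on gene length, at 3.04%.

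Macrophage, lysosome and inflammatory genes were outside the top 5% of random lists matched on gene length by gene-end class. Tyrobp, an adaptor of myeloid receptors, had 7 fragments, Cd68 had 9 and the Fc receptor gene Fcgr3 had 6, all IL-4-only. Atg5 and Ctsb, of autophagy and the lysosome, had IL-4-only peaks of 8 fragments each, and Tnfaip3, an inhibitor of NF-κB, one of 6. The chemokine genes Ccl3 and Ccl4 share 1 peak of 6 fragments. IL-4-only genes numbered 12 of 24 for macrophage identity, 12 of 21 for lysosome and autophagy, 10 of 24 for inflammatory and 5 of 18 for interferon response genes, shares that 11.1%, 6.56%, 34.3% and 84.8% of random lists reached. Lysosome and autophagy genes were in the top 5% of unmatched random lists, at 3.20%.

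Markers of other blood and bone marrow cell types had almost no IL-4-only gene-end peaks past q 0.05. None of the neutrophil, T and NK cell, B cell, stromal and erythroid genes had one, and 1 of 10 dendritic cell genes did: Siglech, a receptor of plasmacytoid dendritic cells, with 6 fragments. Pooled after the data were seen, these 6 lists gave 1 of 66 genes (1.52%) against a median of 16.7% in random lists, and 0% of random lists were as low. Over all peaks, including those of 3 to 5 fragments, the pooled count was 23 of 66 (34.8%), against a random median of 36.4%. The single lists gave 4 of 12 neutrophil, 5 of 14 T and NK cell, 0 of 10 B cell, 7 of 10 dendritic cell, 3 of 10 stromal and 4 of 10 erythroid genes. The dendritic cell list was in the top 5% there, at 3.25% of random lists, and not at q of at most 0.05, at 84.9%. Neuron and hepatocyte genes were at 1 of 12 and 3 of 12 over all peaks and at 3 of 12 and 1 of 12 past q 0.05, together 4 of 24 (16.7%) at each. The random median was 37.5% over all peaks, with 2.51% of random lists at or below, and 16.7% past q 0.05. The 2 pools thus stood below random lists at different thresholds. The strongest among them was at Slc17a6, a vesicular glutamate transporter gene, with 10 fragments at a summit 791 bp from the gene's end.

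**Figure D2:**
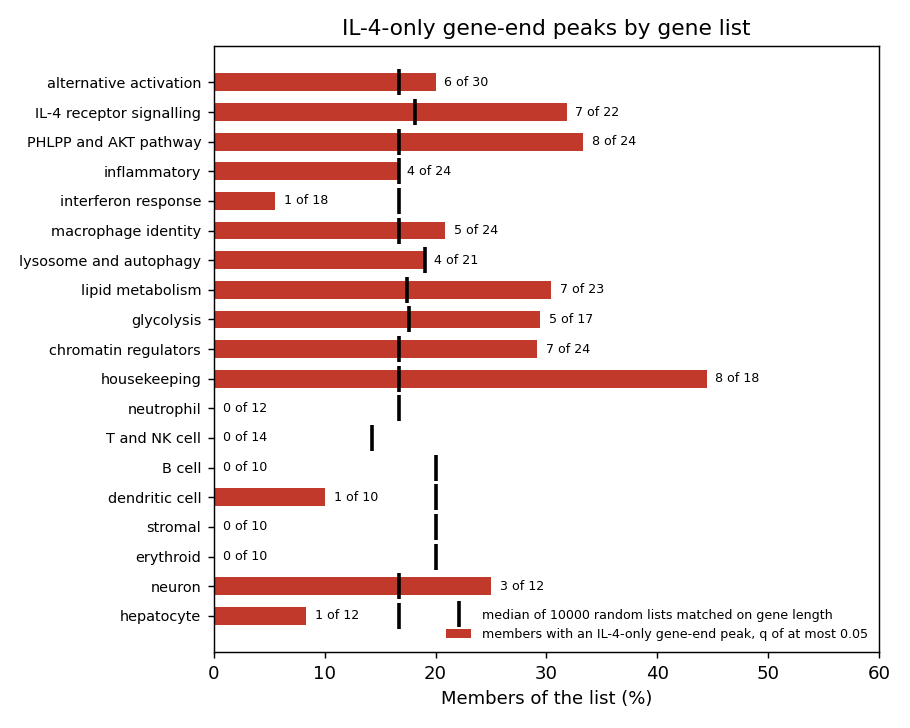
Share of each gene list's measured members with a gene-end peak in the IL-4 list only at q of at most 0.05 (percent, red bars, with the count beside each bar; 1 library per group), with black ticks for medians of 10000 random lists matched on gene length. Housekeeping genes reach 44.4%, and 5 lists of other cell types are at 0.

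Peaks within 50 kb of a gene were more numerous in the longer IL-4 list, with a median log2 ratio of 0.81 over all genes. Stat6 had 25 peaks in the IL-4 list and 4 in the untreated list, Pparg 25 and 6, Il4ra 21 and 6, and Phlpp1 20 and 8, whereas Retnla had 5 and 5 and Chil3 17 and 16. Against random lists with as many peaks, the chromatin regulators (median 1.30), macrophage identity (1.38) and IL-4 receptor signalling genes (1.20) lay highest, with 0.02%, 0.09% and 0.14% of random lists at or above them. Inflammatory genes (1.26), housekeeping genes (1.22) and the PHLPP and AKT pathway (0.91) were at 1.54%, 1.85% and 4.44%. Neighbouring members of a list, such as Ccl3 and Ccl4 or Stat3 and Stat5b, count some of the same peaks. Random lists were drawn without regard to position, so the percentiles of lists with such members can be too extreme. Alternative activation genes had a median of 0.77, with 61.6% of random lists at or above. Lysosome (1.07), lipid (1.00), glycolysis (0.94), interferon (0.95), neutrophil (0.96), T and NK cell (0.92), hepatocyte (0.88), dendritic cell (0.70), stromal (0.63) and neuron genes (0.58) had between 6.64% and 81.6% at or above. B cell (0.35) and erythroid genes (0.45) had 3.13% and 4.72% of random lists at or below them, but neither was that low within 10 kb, within 100 kb, with lists of equal length or at q of at most 0.05. At q of at most 0.05 IL-4 receptor signalling was the only list in the top 5%, and within 10 kb the PHLPP and AKT pathway was the only one. That pathway left the top 5% without chromosome X and within 100 kb. With lists of equal length macrophage identity left it, and lysosome and lipid genes entered it.

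The 2 lists shared few sites. Of the untreated peaks 13039 (8.73%, 8.59 to 8.87) overlapped an IL-4 peak, and shifted peaks gave 4.20%. Of the IL-4 peaks 13048 (5.42%, 5.33 to 5.51) overlapped an untreated peak, against 2.62%. The strong IL-4 gene-end peaks were overlapped far more often, 195 of 461 (42.3%, 37.9 to 46.9) against 4.66% for shifted peaks. The 202 untreated peaks there had a median of 6 fragments. All 461 strong IL-4 gene-end peaks, with or without an untreated peak, had a median of 13. These medians are not paired by site, and the IL-4 peaks were selected for their strength. All 11 strong untreated gene-end peaks overlapped an IL-4 peak, but only 46 of 130 strong untreated peaks away from gene ends did (35.4%).

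Away from gene ends, the strongest IL-4-only peak lay on chromosome 13 from 85127046 to 85127241, with 23 fragments, 62232 bp from the nearest gene end, that of Ccnh. Others lay inside Tbc1d14, on chromosome 5 from 36581727 to 36582484, inside Dcaf11, Rasgrp1, which encodes an activator of Ras, and Hnrnpl, with 16 to 20 fragments. Their summits were 4246, 1460, 22242 and 2170 bp from the nearest gene end. Those in Dcaf11 and Hnrnpl would count as gene-end peaks with the 3 kb window. The strongest untreated-only peaks lay inside Naaladl2, on chromosome 3 from 24552258 to 24552493, on chromosome 3 at 306736 bp from the nearest gene end, that of Negr1, and inside Magi2, with 19, 20 and 19 fragments.

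Most peaks of both lists rested on few fragments. The lowest number at a summit was 4 in the untreated list and 3 in the IL-4 list, held by 48595 peaks (32.5%) and 77667 peaks (32.3%), and the medians were 5 and 4. The lowest local background was 0.936 fragments in the untreated library and 0.643 in the IL-4 library, a ratio of 1.46. Counting peaks of at least 4 fragments, the lists held 149349 and 162994 peaks, a ratio of 1.09 in place of 1.61 for all peaks. At q of at most 0.05 they held 21879 (14.6%) and 30010 (12.5%), and the weakest listed peaks had a q of 0.465 and 0.405.

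**Figure D3:**
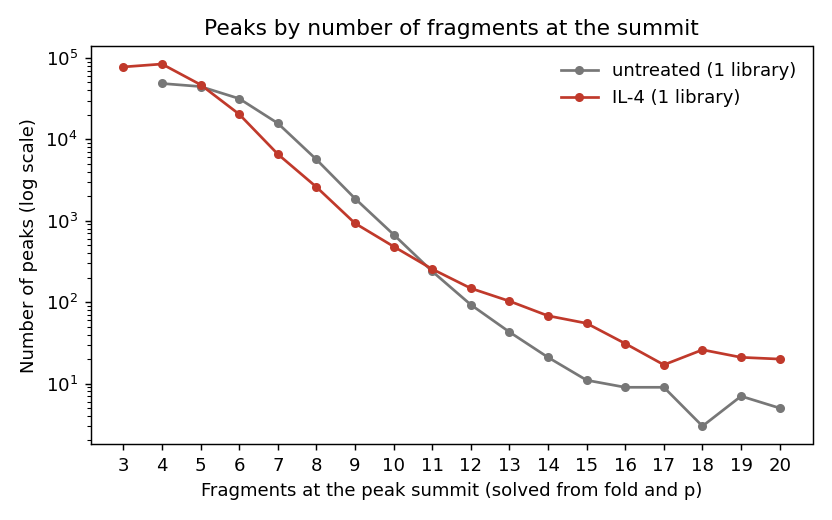
Number of peaks (vertical axis, log scale) by number of fragments at the summit (horizontal axis, 3 to 20) in the untreated (grey) and IL-4 (red) libraries, 1 each, without error bars. The untreated list begins at 4 fragments with 48595 peaks, and the IL-4 list at 3 fragments with 77667.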

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

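The thresholds of q 0.05 and 4 fragments and the density without chromosome X were chosen after the data were seen. So were a −log10 q of at least 5 for the classes of the gene lists and the pooling of lists. The other alternatives were fixed before. No paired analysis was possible because the groups share only 1 replicate number, with 1 library each, and for the same reason no library could be left out. The 3 alternatives for motif shares fixed before were not run, since no genome was used here. Counting all chromosomes moved nothing, as no peak lay off chromosomes 1 to 19 and X. The lists rest on 4 or 5 fragments at the median peak, and this limits every count below. The causes of the shifts were not tested, except that stricter thresholds leave fewer peaks and wider windows take in more.

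The untreated and IL-4 lists held 141 and 799 peaks at a −log10 q of at least 5, 1872 and 3664 at a fold of at least 5, and 21879 and 30010 at q of at most 0.05, with the IL-4 list longer in each. The shared percentages of the untreated and IL-4 lists were 3.10 and 1.92 with 50% reciprocal overlap, 7.78 and 4.83 with summits within 200 bp, 20.6 and 3.63 at a −log10 q of at least 5, 6.07 and 6.04 at equal list length, 2.76 and 2.74 for the strongest 10000, 3.47 and 2.52 at q of at most 0.05, and 6.63 and 6.06 with at least 4 fragments. The gene-end percentages were 1.93 and 3.51 within 500 bp, 8.60 and 11.0 within 3 kb, 7.80 and 57.7 at a −log10 q of at least 5, and 3.73 and 12.0 at q of at most 0.05. At equal list length the IL-4 share was 6.10. The IL-4 share was the higher one in each of these.

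Genes with a gene-end peak in both lists numbered 1502 within 500 bp, 8441 within 3 kb, 329 at q of at most 0.05 and 11 at a −log10 q of at least 5. At these last 2 thresholds, IL-4-only genes numbered 3676 and 564 and untreated-only genes 551 and 1. The number of gene lists in the top 5% for IL-4-only gene ends was 4 with all peaks, 6 with unmatched random lists (lysosome and autophagy and lipid metabolism added), 2 at equal list length (IL-4 receptor signalling and housekeeping), 1 at q of at most 0.05 (housekeeping) and 0 at a −log10 q of at least 5. For peak density it was 6 within 50 kb, 7 at equal list length (lysosome and autophagy and lipid metabolism in, macrophage identity out), 5 within 100 kb and 5 without chromosome X (PHLPP and AKT pathway out of both), 1 within 10 kb, 1 at q of at most 0.05 and 0 at a −log10 q of at least 5, where peaks are so few that the median of each of the 19 lists is 0 and the count shows nothing. Within 10 kb, IL-4 receptor signalling genes lay -0.0352 from the median of random lists (log2) in place of above it, and erythroid genes 0.0850 above in place of below. Other values for single lists and named genes counted as unchanged in 468 cases and as moved in 280. Gene-end shares counted as unchanged within their interval, and named genes within their class. Peak density counted as unchanged when it did not change sides of the random median, whatever its size. The 468 include the density of all 19 lists at a −log10 q of at least 5, so they overstate stability. Of 112 named genes, 104 kept their gene-end class at equal list length, 74 within 500 bp, 69 within 3 kb, 56 at q of at most 0.05 and 21 at a −log10 q of at least 5.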

Other observations

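The tests below were chosen after the results were seen, except those on sites absent from the untreated library and on regions high in both libraries. The regions in the next paragraph were also picked after their values were seen.

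Of the 20 strongest peaks of the untreated list, 17 were shared with the IL-4 list and 2 were at gene ends, and of its 100 strongest 47 were shared and 9 were at gene ends. Of the 20 strongest of the IL-4 list 17 were shared and 13 were at gene ends, and of its 100 strongest 66 and 72. The strongest peak of both lists lay on chromosome 11 from 109011646 to 109012122, inside the non-coding RNA gene Gm36876, with 79 fragments in the untreated list and 49 in the IL-4 list. Others lay inside Kctd16 on chromosome 18 from 40308022 to 40308403 (62 fragments without IL-4 and 26 with it) and inside Aida on chromosome 1 from 183299138 to 183299580 (63 and 37 fragments). A peak on chromosome 17 from 39843415 to 39846660 reached into Rn18s-rs5, a pseudogene of 18S ribosomal RNA, with 145 fragments over a local background of 51.2 without IL-4 and 157 over 44.4 with it. A list of regions prone to artefacts was not used here.

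The overlap between the lists followed the strength of the IL-4 peak at gene ends. Untreated peaks overlapped 4.49% of IL-4 gene-end peaks at a −log10 q under 1 (2.63% for shifted peaks), 8.36% between 1 and 2 (3.12%), 17.6% between 2 and 5 (3.90%) and 42.3% at 5 or more (4.66%). Strong IL-4 peaks away from gene ends were overlapped in 69 of 338 cases (20.4%, against 3.37%). Strong IL-4 peaks had a median width of 455 bp, and 602 bp at a −log10 q of 8 or more.

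The IL-4 list was 1.61 times as long as the untreated list. Peaks at q of at most 0.05 made up 8.90% of the difference, which argues against more strong sites as its main source. Fragments placed at random at the 2 backgrounds gave 2.27 times as many peaks per Mb at the lower IL-4 background, where 3 fragments in place of 4 were enough, and 1.80 or 1.70 times with 0.1 or 0.2 extra copies per fragment. Both cutoffs were already known from the lists, so a ratio over 1 was close to given and adds little support. The lower number of fragments needed may account for part of the longer list. With at least 4 fragments in both lists, the IL-4 list was still 1.09 times as long despite its lower background. The cutoff does not account for that. The simulation gives the direction only, since it used the same copy rate for both libraries and did not match the observed densities. It took the narrowest peak widths, 141 bp untreated and 138 bp with IL-4, as mean fragment lengths, which is an assumption. Without extra copies it gave 30.9 untreated and 70.1 IL-4 peaks per Mb, and with 0.2 extra copies 89.7 and 152. The autosomes held 60.3 and 96.6.

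Strong IL-4 peaks lay at gene ends, and few strong untreated peaks did. The untreated background was 1.46 times that of the IL-4 library, which gives no sign of a shallower untreated library. The background also depends on fragment length and duplicate fragments, which are not known here, so it cannot decide on depth in unique fragments. Untreated peaks overlapped 42.3% of these sites, which argues against sites absent without IL-4 as the whole source of the pattern. The other 266 of 461 sites had no untreated peak. Of the strong IL-4 peaks with no untreated peak, 49.7% still lay at gene ends, against 3.09% at shifted positions. A site with no listed untreated peak may still be raised there, below the lowest listed number of 4 fragments. The share therefore cannot decide on regions high in both libraries as the source. None of the 30 alternative activation genes was among the 575 genes with a strong IL-4 gene-end peak. So few genes could not have made up most of the 575 in any case, so this is no test of IL-4 response genes. No IL-4-only gene at this strength was found in 43.1% of random lists either. At q of at most 0.05, 44.0% of random lists reached the share of the alternative activation list, which lies near their middle. Other IL-4 response genes as the source stay open. With 1 library per group, an effect of IL-4 and a lower enrichment of the untreated library for other reasons cannot be told apart, and both may apply. Without a control antibody library or one from PHLPP1-deficient cells, how much of the gene-end signal comes from PHLPP1 is not known either.

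Few peaks lay on chromosome X: 5.86 per Mb against 60.3 on the autosomes in the untreated list, and 17.2 against 96.6 in the IL-4 list. In the IL-4 list the ratio of X to autosomes was 0.235 (0.222 to 0.248) at the lowest number of fragments and 0.0966 (0.0844 to 0.111) at 3 or more above it, and in the untreated list 0.131 and 0.0579. The fall argues against a fixed share of the chromosome left out of the lists. It is consistent with fewer fragments on chromosome X: random fragments at 50% of the autosomal density gave ratios from 0.0395 to 0.257. No peak lay on chromosome Y in either list, the sex of the mice is not given in the sources used here, and no biological explanation was tested.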
